A study of Rattus norvegicus with 6 samples.

How the data were processed

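RNA from whole cultured rat ovaries was measured on 6 Affymetrix 1-colour arrays, 3 control and 3 treated with 50 ng/ml of recombinant human NT3 for 48 h. Per the labels' protocols, each sample held 2 to 3 ovaries homogenised together, and biotin-labelled cRNA was prepared from total RNA. The authors deposited 1 intensity per probe set and array on a linear scale, and per the submitters' processing notes these signals were made with MAS5, whose version is not given in the sources used here. The table held 31099 probe sets, and the mean signal after trimming 2% at each end was 210.0 on every array, so the deposited intensities shared 1 scale. A scaled signal gives no absolute transcript number, and a change in total RNA per ovary would not appear in it. The median signal per array was 75.0, 71.1 and 71.8 in control replicates 1 to 3 and 74.4, 73.0 and 69.0 in NT3 replicates 1 to 3. No array held values identical to another.

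The design, the tests, the gene lists, the rule for naming genes and the alternatives were chosen before the data were examined, apart from those named as added later. Groups and replicate numbers came from the sample titles. After removing 57 control probe sets, signals were taken to log2 with no further scaling, with 0.1, the lowest positive signal, as a floor for 5 probe sets that held a 0. Probe sets whose mean log2 signal lay below the 40th percentile, 5.37 or a signal of 41.3, were left out, which kept 18625. Detection calls were not used here, so this filter stands in for signal above background. NT3 was compared with control by limma (version 3.58.1 in R 4.3.3) with lmFit and eBayes with an intensity trend, 2-sided, and Benjamini-Hochberg adjustment at 0.05.

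Probe sets were named through the array annotation, in which 20826 had 1 gene symbol, 436 several and 9780 none. Entrez identifiers of 20758 were found in the RefSeq gene table of the GRCr8 assembly, and 0 symbols changed. Probe sets with several symbols or none were tested but not named. For each gene the probe set with the highest mean signal was used, which gave 10600 genes. MAS5 probe sets lie mostly near the 3′ end of a transcript, so that degraded RNA changes signals unevenly between probe sets.

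There were 28 gene lists with 864 genes, of which 719 were in the annotation and 602 were tested. They covered ovarian and neurotrophin biology, general processes, and other cell types that a whole ovary culture could hold. The 27 lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, 2-sided, with adjustment over the lists, and each list's genes were also adjusted over the list alone. Some genes stood in more than 1 list, among them 20 of the 30 measured transition regulators. None of the macrophage, oviduct or interferon genes and 1 of the 40 matrix genes also stood in another list. Genes were named by this rule, leaving out symbols for unnamed loci. Per direction, the 10 genes with the largest change among those with an adjusted p under 0.05 were named, filled up to 10 with those of the lowest unadjusted p and then said not to pass. From each list that passed camera the 4 members with the lowest p in its direction were named, and from each other list up to 2 members with an unadjusted p under 0.05. A set of 20 genes of follicle and neurotrophin biology was given in any case, of which 1 is not reported here.

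The control and NT3 samples share replicate numbers in their titles. Deviations from the group means correlated across probe sets at 0.230, 0.247 and 0.222 for the pairs numbered 1, 2 and 3, and each array correlated best with the array of its own number, the highest correlation with another number being 0.029. The numbers were therefore taken to pair the samples, on the evidence of the data and not of any statement in the labels. That evidence is limited. Deviations from a group mean add up to 0, so positive values for equal numbers lower those for unequal ones. With 3 arrays per group few matchings exist, and this one could be the best by chance. The fit without a block was kept as designed, and the fit with the replicate number as a block is given where it changes a call or moves a count by more than 1.5 times.

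RNA quality was checked with the 3′ and 5′ probe sets of beta-actin and Gapdh. The alternatives were the block, quantile normalization, centring on the median, no filter and a filter at the 60th percentile, an offset of 16, no variance trend, array weights, each array left out in turn, other thresholds, the mean of all probe sets of a gene, an estimated correlation and fry. Added after the data were seen were the block without control replicate 2, both arrays numbered 2 left out, and an estimated correlation with each array left out. With an estimated correlation, camera also takes its degrees of freedom from the arrays and not from the genes, so that a list passes far less easily. The fits and list tests were tested on simulated data with 200 changed probe sets, 50 per size. With the 6 arrays, 10%, 46%, 74% and 90% of changes of 1.41-, 2-, 2.83- and 4-fold were recovered with 4 false calls, and a list shifted by 0.3 on the log2 scale was called at an adjusted camera p of 3.59e-05 with 0 other lists called. The simulated genes and arrays varied independently of each other. In the data, members of some lists varied together, with an estimated correlation of 0.81 for the ribosomal proteins. The simulation therefore could not show whether camera makes false list calls in these data.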

Results

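Gene expression was measured in ovaries of 4-day-old Sprague-Dawley rats that were cultured whole for 48 h, either with no added factor or with 50 ng/ml of NT3. NT3, the product of Ntf3, is a neurotrophin that signals mainly through the receptor kinase encoded by Ntrk3. At this age the rat ovary holds mostly primordial follicles, in which an arrested oocyte is surrounded by flattened granulosa cells. The series title concerns the passage of these follicles to the primary stage, and the comparison asks which transcripts differ when NT3 is present. There were 3 control and 3 NT3 arrays, each hybridised with RNA from 2 to 3 ovaries, and their number limits the precision of every value given here. The labels call the replicates biological but do not say whether they came from separate animals or litters, so p-values measure only the spread between these samples.

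The signal levels of the 6 arrays were alike, with medians from 69.0 to 75.0 and a trimmed mean of 210.0 on every array. Control replicate 2 stood apart in its RNA quality measures. Its 3′ to 5′ signal ratio for beta-actin was 6.83, against 2.42 to 2.91 on the other 5 arrays, and its ratio for Gapdh was 1.70, against 1.09 to 1.25. The beta-actin 5′ signal on that array was 719.8, against 1396.5 to 1914.3 on the others, while its 3′ signal of 4918 lay within their range of 3888 to 4980. Control replicate 2 had 157 genes more than 2-fold from the mean of the other arrays, 33 of them higher and 124 lower, and the other arrays had 18 to 58. The first principal component, which held 50.8% of the variance, set this array at 54.4 and the others between -16.9 and 1.48. The quality measures still moved with the groups when control replicate 2 was left out. The beta-actin ratio was 2.42 and 2.60 in control replicates 1 and 3 and 2.78 to 2.91 in NT3, and the Gapdh ratio 1.09 and 1.14 against 1.21 to 1.25. The spike-in signal, which comes from hybridisation controls and does not measure RNA quality, was 1631 and 1664 against 1791 to 2013. All comparisons below use the 6 arrays, and values without control replicate 2 are given where a call or direction turned, and for some other results.

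**Figure D1:**
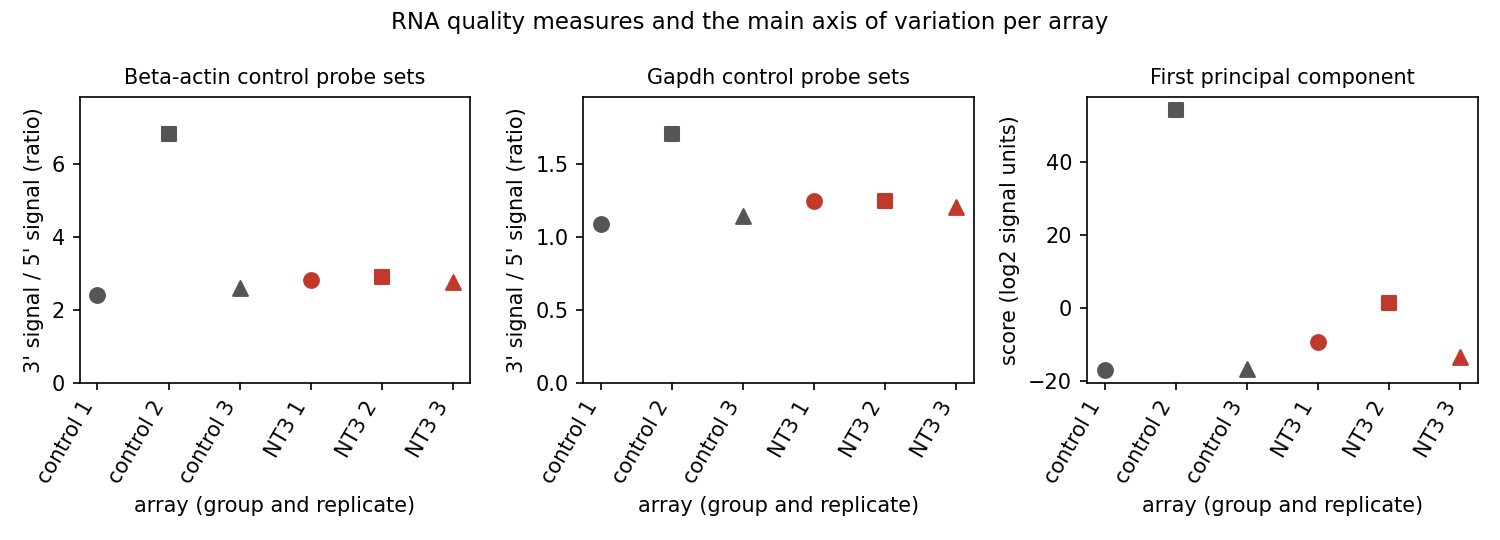
The 3′ to 5′ signal ratios of the beta-actin and Gapdh control probe sets and the score on the first principal component (log2 signal units), with 1 point per array, controls in grey and NT3 in red. Control replicate 2 has a beta-actin ratio of 6.83 and a component score of 54.4, above the other 5 arrays in all 3 panels.

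The tight junction gene Cldn3 and the matrix glycoprotein gene Tnc had the lowest p-values among genes with a higher signal in NT3-treated ovaries. Cldn3 had a mean signal of 64.7 ± 3.10 in control and 126 ± 34.3 in NT3 (SD, n = 3), and Tnc 126 ± 9.29 and 182 ± 19.1. Hspa4, which encodes a heat shock protein of the Hsp110 family, had the lowest p-value among genes with a lower signal, at 295 ± 50.7 in control and 165 ± 46.8 in NT3. None of these differences passed the test across all probe sets. By limma, 0 of 18625 probe sets had an adjusted p under 0.05, the lowest adjusted p was 1.00, and 240 probe sets had an unadjusted p under 0.05, of which 102 were higher and 138 lower in NT3. If all arrays varied independently, chance would give 931 such probe sets, but arrays of the same replicate number deviated together, which lowers that number in a fit without a block. With the replicate number as a block the count was 401, and without control replicate 2 and with no block it was 656. The shared deviations alone are therefore not shown to account for the whole gap. With the block and without control replicate 2, a fit added later that rests on 2 pairs, the count was 962, near the chance number.

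The log2 fold change was 0.92 ± 0.24 (SE) for Cldn3, with an unadjusted limma p of 0.00372, and 0.53 ± 0.15 for Tnc, with 0.00785. Plaur, the urokinase receptor gene, had a log2 fold change of 1.01 ± 0.34 at low signals of 33.8 in control and 65.9 in NT3, on a probe set whose name marks it as shared between transcripts. The genes Dock4 and Tiam1, which encode exchange factors of small GTPases, had log2 fold changes of 0.65 ± 0.23 and 0.45 ± 0.17, and 2 of the 3 other probe sets of Tiam1 went the other way. The other genes with the lowest p-values on this side were Ubr3, Palmd, Srp54a, Anp32a and Ifnar2, at 0.48, 0.83, 0.31, 0.31 and 0.35. For Srp54a, both other probe sets of the gene went the other way. In 9 of these 10 genes, all but Palmd, every NT3 array was above every control array.

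Among genes with a lower signal in NT3, Hspa4 had a log2 fold change of -0.87 ± 0.23 with an unadjusted limma p of 0.00418. Troap, whose product binds the mitotic spindle, had -0.95 ± 0.27, from a mean signal of 63.4 to 32.2. Khk, the ketohexokinase gene, had -0.84 ± 0.27, and Mtm1, which encodes a phosphoinositide phosphatase, had -0.79 ± 0.25. The homeobox gene Cdx2 had -0.71 ± 0.23 at low signals of 55.3 and 34.1. Ly6c, Coro2a, Katnbl1, Retreg2 and Tapt1 had -0.67, -0.64, -0.41, -0.41 and -0.35, and the other probe set of Coro2a and 1 of the 3 others of Katnbl1 went the other way. In all 10 of these genes every NT3 array was below every control array. The genes named on both sides were chosen for a low p in the same arrays, which by itself favours groups that do not overlap. Over all tested probe sets, such separation of the groups occurred in 1085, or 5.83%, where chance gives 10% for independent arrays and the shared deviations of same-numbered arrays lower that share too.

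The median standard error of a log2 fold change was 0.18, so that the 95% interval of the median probe set reached 1.32-fold to either side. In simulated data with the spread of the 6 arrays, limma recovered 46% of 2-fold and 90% of 4-fold changes, but 10% of 1.41-fold changes. The simulated arrays were independent, without the shared deviations of same-numbered arrays. There, 5.00% of unchanged probe sets had an unadjusted limma p under 0.05, against 1.29% of the tested probe sets in the data. Recovery in the real arrays may therefore differ, in a direction that was not tested. Without control replicate 2, limma again gave 0 probe sets at an adjusted p under 0.05, with 656 at an unadjusted p under 0.05. Without control replicate 3 that second count was 420, and with the replicate number as a block it was 401, 174 higher and 227 lower, again with 0 adjusted calls.

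Genes of the extracellular matrix were slightly higher as a group in the NT3-treated ovaries. Of 40 measured members of that list, 31 were higher and 9 lower, with a median log2 fold change of 0.084, or 1.06-fold. The group rose relative to other genes by limma's camera test, at an adjusted p of 0.000609 over 27 lists, but the adjusted p = 0.858 with an estimated correlation between members. The basement membrane gene Nid2 had a log2 fold change of 0.24 ± 0.11 and the collagen gene Col6a1 0.19 ± 0.10. The proteoglycan gene Lum, which has a high signal here, had 2430 ± 577 in control and 2983 ± 177 in NT3 (SD, n = 3). Its log2 fold change was 0.32 ± 0.17 with all arrays and 0.11 without control replicate 2, where its signal was 1766 against 2711 and 2813 in the other controls. Tnc, named above, also belongs to this list. No member passed limma's test, with 0 called over all genes and 0 adjusted over the list alone. The list's median per array was -0.079, 0.028 and -0.092 in control replicates 1 to 3 and 0.14, 0.021 and 0.0048 in NT3 replicates 1 to 3. An exact 2-sided permutation test of the mean score per array gave p = 0.3, where 0.1 is the smallest p that 3 arrays against 3 allow.

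The matrix list had a median of 0.12, with 34 members higher and 6 lower, without control replicate 2, the array with the high 3′ to 5′ ratios, at an adjusted camera p of 3.32e-07, but the adjusted p = 0.939 with an estimated correlation. Before adjustment over the lists, the camera p with an estimated correlation was 0.0428. In that fit all 3 NT3 arrays also had higher 3′ to 5′ ratios than both controls, at 2.78 to 2.91 against 2.42 and 2.60 for beta-actin. Without NT3 replicate 1 the median was 0.040 and the adjusted camera p 0.0589, without control replicate 3 the median was 0.026, and without NT3 replicate 3 it was 0.13. Genes of smooth muscle and pericytes had a median of 0.12 with 12 of 17 members higher and an adjusted camera p of 0.234.

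Markers of macrophages and other leukocytes rose as a group by camera, with 17 of 23 members higher, a median log2 fold change of 0.13 and an adjusted p of 0.0112. The adjusted p = 0.858 with an estimated correlation. The protease gene Ctss had 0.24 ± 0.13, the signalling adaptor gene Tyrobp 0.27 ± 0.15, the leukocyte phosphatase gene Ptprc 0.24 ± 0.17, or 0.11 without control replicate 2, and the lysosomal marker gene Cd68 0.22 ± 0.16. None of the 23 passed limma's test, with 0 called over all genes and 0 adjusted over the list alone. In control replicate 2 the list's median lay at -0.19, the lowest of the 6 arrays, and in NT3 replicate 2 at 0.17, the highest. Without control replicate 2 the median was 0.039 with an adjusted camera p of 0.640, without NT3 replicate 2 it was 0.050 with 0.247, and without control replicate 1 it was 0.11 with 0.0837.

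Markers of oviduct and mesonephric epithelium, which could come with ovaries as attached tissue, rose by camera with 7 of 9 members higher, a median log2 fold change of 0.26 and an adjusted p of 0.0454. The adjusted p = 0.858 with an estimated correlation, and with the replicate number as a block the adjusted p was 0.0585, within a range of 0.00842 to 0.965 over 24 alternatives. Cldn3, at 0.92 ± 0.24, was the 1 member that limma called when adjusted over the list alone, and 0 were called over all genes. The secreted protease inhibitor gene Wfdc2 had 0.41 ± 0.25, the transcription factor gene Pax8 0.26 ± 0.21, with its other probe set going the other way, and the osteopontin gene Spp1 0.28 ± 0.24, or 0.047 without control replicate 2. All 3 NT3 arrays, at -0.044 to 0.34, had a higher list median than the 3 controls, at -0.20 to -0.056. The adjusted camera p was 0.102 without control replicate 1, 0.0681 without control replicate 2, 0.182 without control replicate 3 and 0.275 without NT3 replicate 2, where the medians were 0.23, 0.21, 0.13 and 0.13.

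Interferon-response genes fell as a group by camera, with 21 of 25 members lower, a median log2 fold change of -0.12 and an adjusted p of 0.0454. The adjusted p = 0.858 with an estimated correlation. The antiviral genes Oas1a and Rsad2 had -0.30 ± 0.19 and -0.37 ± 0.28, the immunoproteasome gene Psmb8 -0.18 ± 0.15 and the ubiquitin-like protease gene Usp18 -0.21 ± 0.19, against -0.072, -0.064, -0.049 and -0.030 without control replicate 2. Limma called 0 members over all genes and 0 adjusted over the list alone. Control replicate 2 had the highest list median, 0.37, and NT3 replicate 3 the lowest, -0.40. Without control replicate 2 the median was 0.021 and the adjusted camera p 0.963, with the test's direction still lower. Without NT3 replicate 3 the median was 0.047 with an adjusted p of 0.554, and without control replicate 3 it was -0.16 with 0.148. The median was -0.25, -0.21 and -0.22 without control replicate 1, NT3 replicate 1 and NT3 replicate 2.

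**Figure D2:**
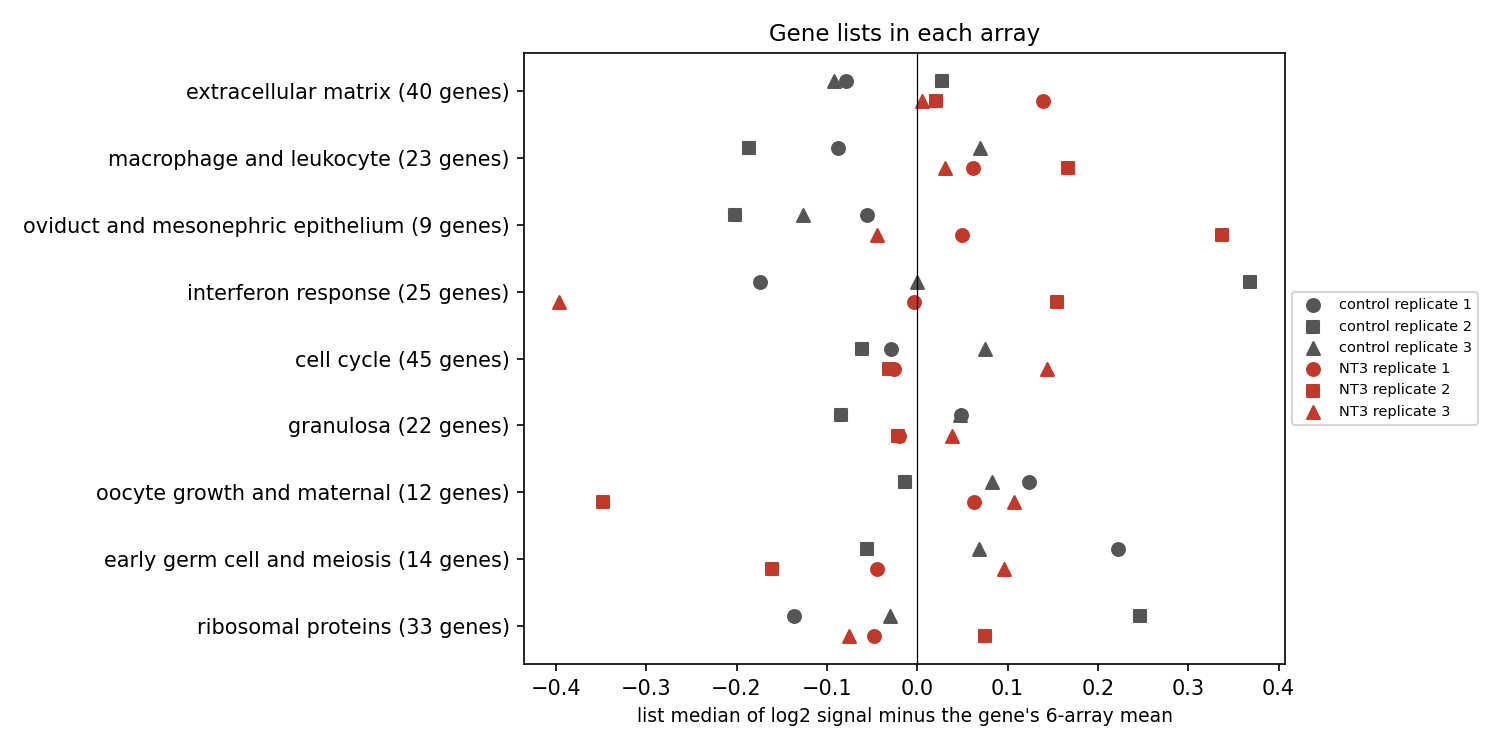
Median over each gene list of the log2 signal minus the gene's mean over the 6 arrays, with 1 point per array, controls in grey and NT3 in red, for the 4 lists that passed camera and 5 others. Control replicate 2 has the highest interferon-response median, 0.37, and NT3 replicate 2 the lowest oocyte median, -0.35.

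Genes of the growing oocyte had a median log2 fold change of -0.12, with 10 of 12 members lower, and did not pass camera (adjusted p = 0.234). Gdf9, the oocyte growth factor gene, had a signal of 1531 ± 345 in control and 1368 ± 395 in NT3 (SD, n = 3), with a log2 fold change of -0.18 ± 0.24, from -0.37 without control replicate 2 to 0.077 over single arrays left out, and the zona pellucida gene Zp3 had 4285 ± 75.4 and 4063 ± 483. The list's median lay at -0.35 in NT3 replicate 2 and between -0.013 and 0.12 on the other arrays. All 12 members were lower without control replicate 2, with a median of -0.12 and an adjusted camera p of 0.00712, but the adjusted p = 0.939 with an estimated correlation. Without NT3 replicate 3 the median was -0.17 with an adjusted camera p of 0.00299, and without NT3 replicate 2 it was 0.049. Early germ cell and meiosis genes had a median of -0.088, 10 of 14 lower, at an adjusted camera p of 0.250. Without control replicate 2 their median was -0.16 with 0.00378, and without NT3 replicate 3 it was -0.12 with 0.0355. With an estimated correlation the adjusted p = 0.939 without control replicate 2, and no list had an adjusted p under 0.532 without NT3 replicate 3. Limma called 0 members of either list over all genes and 0 adjusted over the list alone.

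Granulosa genes had a median of -0.060 (camera adjusted p = 0.492), which was -0.18 without control replicate 2 and 0.022 without control replicate 3. Amh, the anti-Müllerian hormone gene of growing follicles, had a log2 fold change of -0.32 ± 0.19. The granulosa transcription factor gene Foxl2 had 0.16 ± 0.18, and -0.031 to 0.30 with single arrays left out. Theca and steroidogenesis genes had a median of 0.019 but a mean and a test direction below 0 (camera adjusted p = 0.939). Regulators of the primordial to primary transition had a median of 0.013, with 16 of 30 members higher (camera adjusted p = 0.584), and 0.058 without control replicate 2 but -0.025 without control replicate 3. Of these, the oocyte receptor gene Kit had 0.24 ± 0.49 and its ligand gene Kitlg -0.061 ± 0.18, while Foxo3 and Cdkn1b, which restrain follicle activation, had -0.011 ± 0.16 and -0.17 ± 0.16. Foxo3 had 0.12 without control replicate 2, and 2 of the 3 other probe sets of Kitlg and 1 of the 2 of Foxo3 went the other way. Kit, at a signal of 23.2 in control replicate 2 against 88.0 and 103 in the other controls, had -0.44 without that array. Bmp15 had 0.27 ± 0.53 with all arrays and -0.45 without it. Igf1 and Pdgfra had 0.049 ± 0.11 and 0.11 ± 0.098.

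The list of neurotrophins and receptors had a median log2 fold change of -0.066, with 10 of 12 members lower and an adjusted camera p of 0.273. No neurotrophin gene was among these 12. Besides the receptor genes Ntrk2 and Ngfr, they were genes of sortilin-family, adaptor and other partner proteins, such as Sort1, Shc1 and Frs2. The median was 0.021 without control replicate 2, with 7 members higher and 5 lower and the test's direction still lower. The receptor genes Ntrk2 and Ngfr had -0.075 ± 0.22 and -0.22 ± 0.27, and 2 of the 4 other probe sets of Ntrk2 went the other way. Ntf3 and Ntrk3 lay below the signal filter and were not tested, at 42.1 ± 10.8 and 25.8 ± 10.9 in control and 39.2 ± 15.8 and 21.0 ± 2.85 in NT3 (SD, n = 3). The log2 fold change of Ntrk3 was -0.21 ± 0.44 with all arrays and 0.093 without control replicate 2. Fgf2 was also below it, at 22.1 ± 3.99 and 25.8 ± 0.72. No probe set carried the name of Nobox, Figla or Ddx4 in the annotation used. None of the 13 tested genes of this fixed set had an unadjusted limma p under 0.05 with all 6 arrays. Of the 16 genes of the set that had a probe set, Amh, Fgf2 and Pdgfra, 3 in all, kept their direction whichever array was left out.

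**Figure D3:**
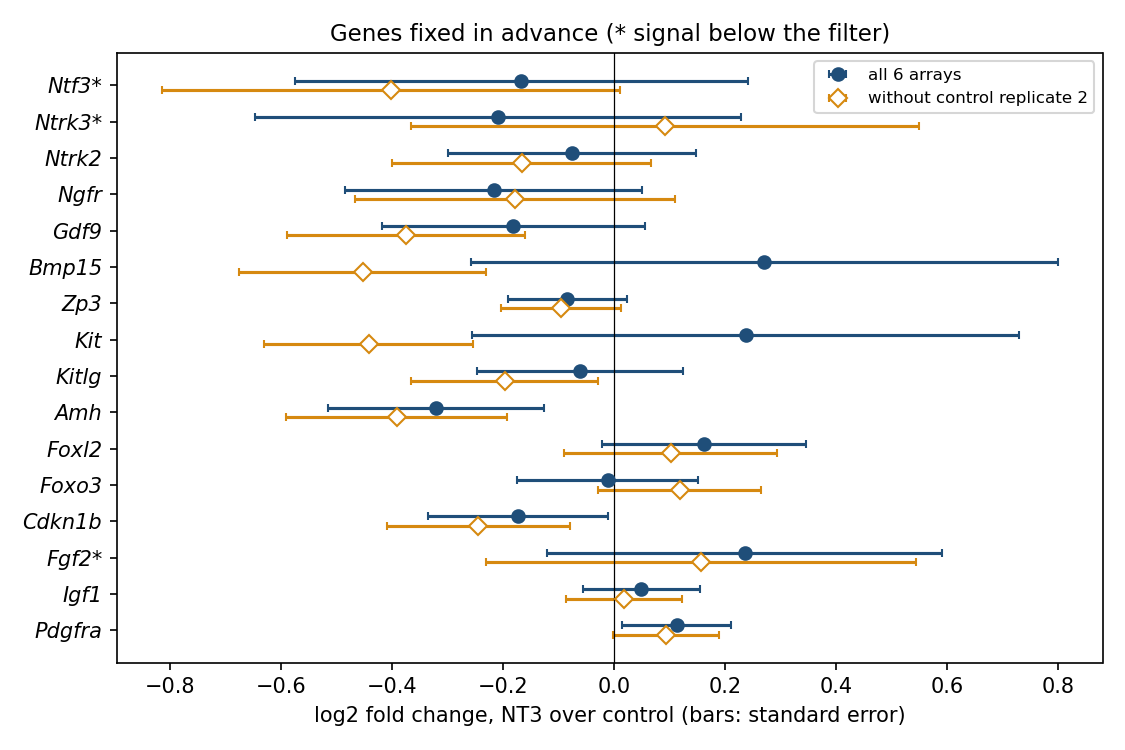
Log2 fold change, NT3 over control, of 16 genes fixed in advance, with bars for the standard error, from all 6 arrays (filled) and without control replicate 2 (open). Kit and Bmp15 lie at 0.24 and 0.27 with all arrays and at -0.44 and -0.45 without control replicate 2.

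Of the signalling pathways, MAPK-responsive genes had a median of 0.043 and PI3K and mTOR genes 0.013, with adjusted camera p of 0.492 and 0.922. TGF-beta and BMP genes had -0.020 with 0.922, and 0.017 without control replicate 2. Cell cycle genes had a median of 0.048 with 31 of 45 higher and an adjusted camera p of 0.128. That p was 0.00378 without control replicate 3, 0.0291 without NT3 replicate 1 and 0.00196 without NT3 replicate 2, where the medians were 0.090, 0.065 and 0.076, while without NT3 replicate 3, which had the highest list median of 0.14, it was -0.010. With an estimated correlation no list passed without these arrays, the lowest adjusted p being 0.928, 0.965 and 0.812. Without control replicate 2, the cell cycle median was 0.030 with 24 members higher and 21 lower, at an adjusted camera p of 0.805.

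Ribosomal protein genes had a median of -0.029, with 26 of 33 lower and an adjusted camera p of 0.401, and control replicate 2 had their highest list median, 0.25. Their direction turned without control replicate 2, with a median of 0.073 and an adjusted camera p of 0.00378, but the adjusted p = 0.939 with an estimated correlation. Without control replicate 1 the median was -0.12 with 7.6e-05, and without NT3 replicate 2 it was -0.075 with 0.0473, and with an estimated correlation no list passed there, the lowest adjusted p being 0.900 and 0.812. Oxidative phosphorylation genes had a median of 0.016 with 28 of 44 higher and an adjusted camera p of 0.250. That p was 0.00815 without control replicate 2, 0.0479 without control replicate 3 and 0.0378 without NT3 replicate 1, where the medians were 0.065, 0.066 and 0.054, while without control replicate 1 it was -0.036. With an estimated correlation the adjusted p = 0.939 without control replicate 2, and no list passed without the others, the lowest adjusted p being 0.928 and 0.965. Inflammation and injury genes had a median of 0.033, with 13 members higher and 12 lower (camera adjusted p = 0.234). Plaur and the matrix protease gene Mmp3, at 0.57 ± 0.25, are among those higher. Without NT3 replicate 3 the list's median was 0.093 with an adjusted camera p of 0.00894. No list passed there with an estimated correlation (lowest adjusted p = 0.532). Without control replicate 1 the inflammation median was -0.0099.

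Of the other metabolic and stress lists, glycolysis and hypoxia had a median of 0.031, or -0.023 without control replicate 2, cholesterol synthesis 0.036, p53 and apoptosis 0.028 and chaperones and the unfolded protein response -0.0016, with adjusted camera p of 0.368, 0.561, 0.368 and 0.944. The chaperone list includes Hspa4 and the stress-response gene Chac1, at -0.48 ± 0.21, and also Manf, named after its values were seen, at 0.23 with an unadjusted limma p of 0.0490, and 16 of its members were higher and 17 lower. Among other cell types, endothelial genes had a median of -0.033 but a mean and a test direction above 0 (camera adjusted p = 0.898). The endothelial median was -0.067 without control replicate 2, with 15 of 20 members lower and the test direction below 0, and it ranged from -0.14 without NT3 replicate 1 to 0.10 without NT3 replicate 2. Neuron and Schwann cell markers had a median of -0.023 and adipose markers -0.096, with adjusted camera p of 0.795 and 0.273. Erythroid markers had -0.11 with 0.368, and -0.25 with 0.0291 without NT3 replicate 1, where no list passed with an estimated correlation (lowest adjusted p = 0.965). Surface epithelium and mesothelium markers had 0.039 with 0.368, 0.12 with 0.0434 without control replicate 2, 0.12 with 0.0101 without NT3 replicate 3, and -0.080 without NT3 replicate 2. With an estimated correlation the adjusted p = 0.939 without control replicate 2, and the lowest of any list was 0.532 without NT3 replicate 3. Smooth muscle and pericyte markers passed without NT3 replicate 3, at 0.15 with 0.0103, but not with an estimated correlation, where the lowest adjusted p of any list was 0.532. Of skeletal muscle, 3 genes were measured, with a median of 0.10, too few for a test. In each of the lists that did not pass camera, limma called 0 members over all genes and 0 adjusted over the list alone.

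None of the 4 list calls held with an estimated correlation, where the lowest adjusted camera p was 0.858. Before adjustment the camera p there was 0.0940 for matrix, 0.0715 for oviduct, 0.193 for macrophage and 0.432 for interferon genes. The estimated correlations of these lists were 0.11, 0.043, 0.21 and 0.46, in the same order. Limma's fry tests a list against no change and not relative to other genes. With fry, 0 lists had an unadjusted p under 0.05 and the lowest adjusted p was 0.910. Without control replicate 2, where the quality measures separated the groups, camera called 6 lists, and 0 with an estimated correlation, where the lowest adjusted p was 0.939. With each other array left out and an estimated correlation, camera also called 0 lists, with lowest adjusted p from 0.532 to 0.965.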

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

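The block without control replicate 2, leaving out both arrays numbered 2, and the estimated correlation with each array left out were tests chosen after the results were seen. With all 6 arrays limma gave 0 probe sets at an adjusted p under 0.05 and 240 at an unadjusted one. The adjusted count stayed at 0 in every alternative but the block without control replicate 2, which called 4 on 2 pairs, and 73 probe sets had an unadjusted p under 0.05 and at least 1.5-fold. The unadjusted count was 401 with the block, 752 without a filter, where more probe sets were tested, 123 with the 60th percentile, 377 without a trend, 585 with array weights, 962 with the block without control replicate 2, 514 without the pair numbered 2, and 176 to 656 with single arrays left out. For probe sets higher in NT3 (102) the counts were 174, 280, 59, 301 with array weights, 399, 211 and 46 to 282. For those lower (138) they were 227, 472, 64, 226 without a trend, 284, 563, 303 and 119 to 374. Of 673 values of lists under alternatives, 594 kept their side of the threshold and, apart from 69 with no call on either side, their direction, while 51 lost a call, 22 gained one and 6 reversed. The 6 reversals were the ribosomal list without control replicate 2 (0.073), the interferon list with array weights (0.033) and without NT3 replicate 3 (0.047 at the preset and at the estimated correlation), and the macrophage list without the pair numbered 2 and with the block without control replicate 2 (0.022 in both, where the test pointed down). The 4 lists that passed lost the call with an estimated correlation and with fry, where the medians stay by construction at 0.084 for matrix, 0.13 for macrophage, 0.26 for oviduct and -0.12 for interferon, and with an estimated correlation without control replicate 2, at 0.12, 0.039, 0.21 and 0.021. No list passed with an estimated correlation without control replicates 1 or 3 or NT3 replicates 1, 2 or 3 either, where the medians were 0.069, 0.026, 0.040, 0.095 and 0.13 for matrix, 0.11, 0.18, 0.16, 0.050 and 0.16 for macrophage, 0.23, 0.13, 0.24, 0.13 and 0.28 for oviduct and -0.25, -0.16, -0.21, -0.22 and 0.047 for interferon. With the block the oviduct list lost its call at 0.26 (adjusted p = 0.0585, in a range of 0.00842 to 0.965 over 24 alternatives), and the block changed no other call. Without the pair numbered 2, and with the block without control replicate 2, the oviduct list stood at 0.087 and the interferon list at -0.082. The interferon list also lost its call with quantile normalization (-0.13), without a filter (-0.12) and without a trend (-0.12), and the macrophage list without a filter (0.12) and with array weights (0.053). With array weights, calls were gained by the oocyte (-0.11), early germ cell (-0.14), oxidative phosphorylation (0.044) and smooth muscle lists (0.16), and the cell cycle list gained one with the mean of all probe sets (0.060). With single arrays left out, medians ranged from -0.18 to 0.049 for oocyte, -0.16 to -0.030 for early germ cell, -0.010 to 0.090 for cell cycle, -0.036 to 0.066 for oxidative phosphorylation, -0.12 to 0.073 for ribosomal, -0.0099 to 0.093 for inflammation, -0.25 to 0.047 for interferon, 0.026 to 0.13 for matrix, 0.025 to 0.15 for smooth muscle, 0.039 to 0.18 for macrophage, -0.25 to -0.025 for erythroid, -0.080 to 0.12 for surface epithelium and 0.13 to 0.28 for oviduct. Of the lists with no call under any array left out, medians ranged from -0.18 to 0.022 for granulosa, -0.12 to 0.053 for theca, -0.025 to 0.058 for transition regulators, -0.11 to 0.021 for neurotrophins, -0.011 to 0.059 for MAPK, -0.040 to 0.037 for PI3K, -0.018 to 0.017 for TGF-beta, -0.0061 to 0.052 for cholesterol, -0.023 to 0.071 for glycolysis, -0.015 to 0.028 for chaperones, -0.0018 to 0.064 for p53, -0.14 to 0.10 for endothelium, -0.16 to 0.043 for neuron and -0.22 to -0.034 for adipose. The 60th percentile left too few genes for a value of the oviduct and erythroid lists. The cause was not tested for these changes, except where fewer probe sets or arrays or the construction of the test is named. The 768 values of 49 named genes stayed without a call, 23 of them with the other direction, and the 20 genes with the lowest p kept theirs in all 310. These 20 were chosen for a low p in the same arrays, which by itself favours a stable direction. No detection call was used, so signals near the filter, at 41.3, limit what can be said of dim genes such as Ntf3 and Ntrk3.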

Other observations

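The test of another cell mix in control replicate 2 and the counts of probe sets over other splits were chosen after the results were seen. The fits without control replicate 2 and with an estimated correlation were planned, but they were taken as tests of the explanations for the matrix and macrophage lists only after their results were seen. The block without control replicate 2 was added later too.

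Control replicate 2 differed from the other arrays in whole groups of genes. Its interferon-response genes had a median deviation of 0.44 on the log2 scale from the mean of the other arrays, against -0.48 to 0.19 on the others, and its ribosomal protein genes 0.30, against -0.16 to 0.090. Both lay above all 1000 random lists of the same size and matched signal. Isg15, an interferon-induced gene, had a log2 fold change of -0.49 ± 0.51 in NT3 over control with all 6 arrays and 0.0035 without control replicate 2. NT3 replicate 2 had the lowest oocyte list median, -0.35, and the lowest early germ cell median, -0.16, with the highest medians of the surface epithelium and oviduct lists, 0.29 and 0.34.

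Without control replicate 2, some members of the matrix list differed more and others less, though none passed limma's adjusted test (adjusted p = 1.00). Among those that differed less were Lum, at 0.11 without that array and 0.32 with it, and Fn1, at 0.12 and 0.24. The collagen genes Col1a1 and Col1a2 and the proteoglycan gene Bgn, chosen after their values were seen, had log2 fold changes of 0.34 ± 0.098, 0.29 ± 0.12 and 0.36 ± 0.11 without that array, and 0.14, 0.14 and 0.13 with it. Other collagen genes had smaller or opposite values without it, among them Col3a1 at 0.12 and Col15a1 at -0.30. Eng, which encodes a co-receptor of TGF-beta in endothelium, had 0.62 ± 0.12 without control replicate 2 and 0.35 with it (limma, unadjusted p = 0.147). Its signal was 190, 322 and 177 in control replicates 1 to 3 and 284, 297 and 263 in NT3, so control replicate 2 lay above every NT3 array. Eng was called when adjusted over the endothelial list alone without that array, in a list with 15 of 20 members lower. The block without control replicate 2, on 2 pairs, called 4 probe sets, Hnrnpa2b1 at -0.65 and 3 probe sets with no gene symbol at 1.12, -1.04 and -1.41. Hnrnpa2b1 had 0.093 with all 6 arrays, the opposite direction.

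Control replicate 2 stood apart from the other 5 arrays. RNA degradation may contribute, since its beta-actin and Gapdh 3′ to 5′ ratios, 6.83 and 1.70, both lay above the highest of the other arrays, 2.91 and 1.25. Noise specific to single probe sets was left undecided, since deviations on that array correlated at 0.278 (95% bootstrap interval 0.241 to 0.311) between pairs of probe sets of 2754 genes, which lies between the bounds set in advance, and the other arrays had 0.252 to 0.311. Another cell mix may also play a part, as 1 of 8 cell type lists, macrophages and leukocytes, had a larger deviation there than on any other array and, at -0.22, lay at percentile 0.3 of random lists. No biological explanation was tested, since the labels name no difference between this sample and the other controls.

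The matrix list was higher in NT3, and control replicate 2 alone does not account for it, as the adjusted camera p was 3.32e-07 without that array, in a range of 5.8e-10 to 0.965 over 25 alternatives. Members that vary together between samples of 1 group may account for the low p, but the fit with an estimated correlation cannot decide this. Its adjusted camera p was 0.858, and 0.939 without control replicate 2. That fit also takes its degrees of freedom from the few arrays, so a list can hardly pass there whatever its correlation. Before adjustment these camera p were 0.0940 and 0.0428. More mural cells in the NT3 samples cannot be told apart from a change in matrix genes, because the smooth muscle and pericyte list had an adjusted camera p of 0.180 without control replicate 2 and its median of 0.11 had a 95% bootstrap interval of -0.20 to 0.33, which includes the matrix median of 0.12. That interval measures the spread among the 17 members of the list and not the spread between arrays. RNA quality stays open as well, since without control replicate 2 every NT3 array had a higher beta-actin ratio (2.78 to 2.91) than both controls (2.42 and 2.60), the arrays with the lowest matrix medians (-0.079 and -0.092), although control replicate 2, at a ratio of 6.83, had 0.028. NT3 treatment itself stays open as the biological explanation.

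The macrophage and leukocyte list was also higher in NT3. Control replicate 2 may account for this, since without it the median went from 0.13 to 0.039 and the adjusted camera p to 0.640, in a range of 0.000385 to 0.965 over 25 alternatives. The call was also lost without NT3 replicate 2, at a median of 0.050 with an adjusted camera p of 0.247. Without control replicate 1 it was lost too, at 0.11 with 0.0837, so the call does not depend on control replicate 2 only. The members with the highest array signals, Cd48, Lyz2 and Cd14, had log2 fold changes of 0.17 ± 0.19, 0.13 ± 0.11 and 0.059 ± 0.14, and Cd48 had a signal of 1341 in control replicate 2 against 1954 to 2334 on the other arrays. Of the 29 fixed members 23 lay above the signal filter and were tested, and 0 of these stood in another list. An effect of NT3 on leukocytes in the culture stays open.

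The 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05. The real split had 0 probe sets at an adjusted limma p under 0.05, as did the highest other split, so 10 of 10 had as many. It had 240 at an unadjusted p under 0.05, where the highest other split had 1977, and 9 of 10 had as many. It had 4 lists past camera's threshold, where the highest other split had 9, and 7 of 10 had as many. The matrix list had its lowest adjusted camera p, 0.000609, in the real split, but also passed in 2 others, at 0.0026 with control replicates 1 and 3 and NT3 replicate 2 against the rest, which parts all pairs, and at 0.00428 in the split with 1977 probe sets. The split with 1977 set control replicates 1 and 3 with NT3 replicate 3 against the rest, several times the real count, which points to a structure of the samples other than treatment. It keeps both arrays numbered 2 together, and also those numbered 3, so their shared deviations could raise its count. The same split follows the order of the RNA quality measures, with beta-actin ratios of 2.42 to 2.78 against 2.82 to 6.83 and Gapdh ratios of 1.09 to 1.21 against 1.25 to 1.70. It also follows the spike-in signals, at 1631 to 1791 against 1876 to 2333, which come from hybridisation controls and do not measure RNA quality. Pairing and RNA quality cannot be told apart as the source of this count. Among the 3 other splits that part all pairs of equal number, as the real one does, the counts were 212 to 406 probe sets and 2 to 6 lists. The remaining splits keep a pair together on each side and had 675 to 1977 probe sets and 3 to 9 lists.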
